A study of Mus musculus with 2 samples.

How the data were processed

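The series holds 2 samples of the mouse cell line 661W, 1 cultured without and 1 with choline for 3 days, each hybridised as Cy3-labelled RNA to 1 Agilent single-colour array. Groups were taken from the treatment given in the labels. Total RNA was amplified and labelled with a low-input kit, per the labels' protocols. The scanner files were made with Agilent Feature Extraction 12.1.1.1, per the submitters' processing notes. The deposited scanner files give intensity values per spot. Per the file headers, the processed signal intensity is background-subtracted and detrended within the array, with no normalization between arrays, and a processed error accompanies each spot. The deposited value table holds a ratio, the processed signal over a constant of each array. It is linear, and its order and direction follow the scanner values with no centring of genes. Its medians were 0.0358 for the choline-deficient and 0.0337 for the choline-sufficient array. Its constants, 1609 and 1280, equal the arrays' 75th percentiles, so it gives the same differences as the main setting used here. How the authors describe this step is not given in the sources used here.

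Processed signals were read in R 4.3.3 with the data.table package (version 1.17.8) and set to log2 minus the array's 75th percentile over non-control spots. Control spots and spots marked as outliers by the scanner software (92 and 86 non-control spots) were left out. Spots of a probe were averaged on the log2 scale. A probe was measured when it was well above background by the software's call and not saturated on both arrays, which held for 26461 of 39426 probes. A gene's value was the mean over its measured probes. Of 5150 genes with 2 or more such probes, 551 were at least 2-fold apart, and the probes of 21 of these had opposite signs. Gene names are those of the files. The accessions of 74.8% of probes were found in a RefSeq table of assembly GRCm38.p6, and 0 of these carried another symbol there. Probe positions are on mm9 per the file headers and only 9.23% of them fell inside the same gene on GRCm38.p6, so exon and UTR annotation was not used here. List members were matched by symbol or by a synonym in the RefSeq list, which placed 863 of 873 written members.

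With 1 array per group no test across samples was possible. Genes were counted at a fixed size of 2-fold, and list members at 1.5-fold. For each of 38 lists written before the data were examined, the median log2 difference was placed among 10000 random lists of the same size, drawn from all measured genes and matched on mean level in 20 bins. A list was called above or below when its percentile was over 97.5 or under 2.5. These percentiles describe the 2 arrays and are not p-values. The error of a difference was propagated from the processed errors of both arrays. The software's model sets a floor under it. Over 268 probes with at least 8 of their 10 spots above background on both arrays, the SD of the difference between spots had a median of 0.05. The number of arrays limits the precision of every comparison.

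The genes named were set by a rule written before the data were examined. It takes the 12 largest differences in each direction among genes with a proper symbol, probes of one sign and a size over 2 times the error. It adds every measured member of the choline uptake and CDP-choline list, up to 4 members with the largest differences from each other list, and up to 5 genes per direction with the largest bound among those above background on 1 array. Some genes that this rule names are not reported here. Genes named because they were well above background on neither array were chosen after their values were seen. They are Lum, Crx, Nrl, 5 choline transporter genes and those so named in the inflammatory, glial, cone and choline oxidation lists. The genes of the inflammatory, glial and cone lists named as above background on 1 array only were also chosen then.

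The alternatives set before the data were examined were scaling to the median, quantile normalization, cyclic loess, normexp background correction with an offset of 50 in limma 3.58.1, the deposited value table, no filter on dim probes, a stricter filter keeping the brighter of the measured probes (13617 genes), the brightest probe of a gene, other fold sizes, and a size over 2 errors. Scaling to the mean of 5 bright spike-in probes was added after the data were seen. Lists, counts and errors were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The scripts were tested on simulated data. Among 19816 simulated genes with spot noise of 0.05, the count at 2-fold recovered 0 of 50 genes set at 1.5-fold, 30 of 50 at 2-fold, 50 of 50 at 3-fold and 50 of 50 at 4-fold, with 0 unchanged genes counted. This noise held no variation between arrays or cultures. The run therefore checks the arithmetic and gives no false-positive rate for the real arrays. Of 100 simulated lists of 25 genes with no shift 8 fell outside the central 95%, and of 100 shifted by 0.5 log2 96 were above it.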

Results

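The series measured gene expression in 661W, a mouse photoreceptor cell line with cone-like features. The cells were grown for 3 days in DMEM/F12 medium either lacking or containing choline, the precursor of phosphatidylcholine and acetylcholine. The labels put choline in the sufficient medium at 8.98 g/L, a high figure for a culture medium that could not be checked here. Total RNA of each condition was hybridised to 1 Agilent single-colour mouse array. The design text mentions pooling from 4 dishes and does not say whether these were per condition. The comparison therefore rests on 1 choline-deficient and 1 choline-sufficient array, both on the same slide. There were no replicates, so no difference has a replicate check and no p-value is given. Each array carried 43020 non-control spots for 39429 probes. On the choline-deficient array 30435 spots (70.7%) were well above background, against 29467 (68.5%) on the choline-sufficient array, and 0 spots were saturated. Both arrays measured 19816 genes, and 8434 further genes were well above background on neither array. Differences are log2 values of the choline-deficient minus the choline-sufficient array. No gene on the array was used to check choline status, so the direction of every difference rests on the labels. The error after each ± is the scanner software's estimate, with a median of 0.20. It covers the array measurement and not the variation between cultures. Probe positions are those of the array's files, on the mouse build mm9.

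The comparison asked how expression in 661W cells differs when choline is withheld. Genes of the extracellular matrix, of the inflammatory and NF-kB list, of the hypoxia response, of glycolysis and of cholesterol synthesis were on the whole higher on the choline-deficient array. Genes of the integrated stress response and of autophagy were on the whole lower. Of the 19816 measured genes, 1520 were at least 2-fold higher and 769 at least 2-fold lower on the choline-deficient array. The largest difference among genes higher on that array was in Il1rl1, the receptor of interleukin-33 (NM_010743, chromosome 1, 40504769 to 40504828), at 39.2-fold, a log2 difference of 5.29 ± 0.20. It was followed by Gfra2, a co-receptor of the growth factor neurturin, at 31.1-fold, the synaptic vesicle priming gene Unc13c at 20.2-fold and the chemokine Ccl9 at 18.1-fold. The others among the 12 largest were Edil3, Nrsn1, Col5a3, Col1a1, Car9, Csgalnact1, Il34 and Cthrc1, between 11.9-fold and 18.0-fold higher. Among genes lower on the choline-deficient array, Avil, which encodes the actin-binding protein advillin (NM_009635, chromosome 10, 126453541 to 126454065), differed most, at 119.9-fold lower and a log2 difference of -6.91 ± 0.21. The aldo-keto reductase gene Akr1b7 was 51.0-fold lower, the secreted carbonic anhydrase gene Car6 38.9-fold lower, and Chchd10, a gene of a mitochondrial protein, 23.0-fold lower. Fibin, Ifitm6, Mamdc2, B4galnt2, Hoxb9, Saa3, Pi16 and Nat8 completed the 12, between 17.8-fold and 36.0-fold lower. Both sets of 12 were ranked among genes measured on both arrays that met the naming rule. Genes above background on 1 array only were ranked apart, with folds of up to 69.4, given as lower bounds or as ratios to a dim signal. Of the 24 genes in these 2 sets 23 were measured by 1 probe each. Some folds rest on a dim signal. On the choline-sufficient array Gfra2, Ccl9 and Edil3 had log2 levels of -7.53, -7.13 and -7.06. On the choline-deficient array Fibin had -7.44. The errors of these 4 differences were between 0.255 and 0.304. Higher genes made up 66.4% of those at least 2-fold apart when the arrays were scaled to their 75th percentile, 53.7% when scaled to their medians and 85.6% when scaled to spike-in probes. The last choice was made after the data were seen. Relative to the main scaling, the median of all genes moved by -0.119 with the second scaling and by 0.271 with the third. These are constants for all genes, so they move list medians and those of random lists alike.

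The extracellular matrix and fibroblast list had the largest shift of the 38 lists fixed before the data were examined. Of its 29 measured members 25 were at least 1.5-fold higher on the choline-deficient array and 1 was lower. The list's median was 1.96, above all 10000 random lists of the same size and matched expression, whose central 95% ran from -0.34 to 0.10. The type I collagen gene Col1a1 (NM_007742, chromosome 11, 94813115 to 94813174) was 13.5-fold higher, with a log2 difference of 3.75 ± 0.20. The matrix glycoprotein gene Tnc was 9.86-fold higher, the collagen crosslinking enzyme gene Loxl2 9.69-fold and the type VI collagen gene Col6a2 8.92-fold. Markers of Muller glia and astrocytes, included because the retina holds these cells, were also higher, with 8 of 13 members at least 1.5-fold higher, 1 lower and a median of 0.98 (percentile 99.99). The glial markers Kcnj10 and Sox2 were well above background on neither array, and Rlbp1 only on the choline-deficient array. The list therefore does not show that glial cells were present. Dkk3 was 9.14-fold higher, the transcription factor gene Sox9 5.30-fold and the glutamate transporter gene Slc1a3 3.17-fold, while Apoe was 3.29-fold lower. Lum, a fibroblast gene of the matrix list, was well above background on neither array.

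**Figure D1:**
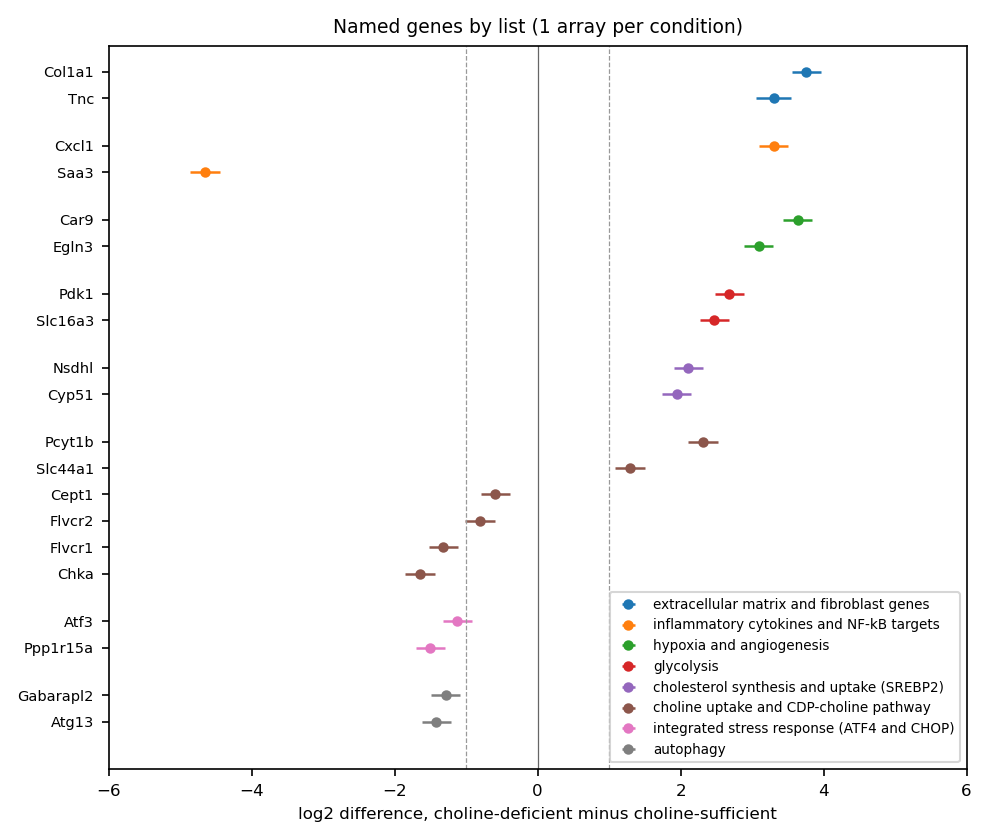
Log2 difference, choline-deficient minus choline-sufficient, of the 2 genes with the largest differences in each of 7 lists and of the choline genes at least 1.5-fold apart, with 1 point per gene and bars of ± 1 scanner error. Dashed lines mark 2-fold. The matrix, hypoxia, glycolysis and cholesterol genes shown lie to the right of the line for 2-fold higher, Cxcl1 and Saa3 of the inflammatory list lie at 3.30 and -4.65, and the choline genes lie on both sides of 0.

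Inflammatory cytokines and NF-kB targets had a median of 1.71, above all 10000 random lists. Of the 25 measured members 16 were at least 1.5-fold higher and 4 lower. The list was written with 34 genes. Of these Il1a, Il1b, Tnf, Ccl20, Cxcl2, Csf3 and Icam1 were well above background on neither array. Ccl8 and Csf2 were so only on the choline-deficient array. The median therefore does not cover these genes. It was 1.198 with no filter on dim probes, again above all 10000 random lists. The neutrophil-attracting chemokine Cxcl1 was 9.88-fold higher (3.30 ± 0.20) and the monocyte-attracting chemokine Ccl7 9.02-fold higher (3.17 ± 0.20). In the opposite direction, the acute-phase gene Saa3 was 25.1-fold lower and Lcn2, which encodes the iron-carrier-binding lipocalin 2, was 8.85-fold lower. Immediate early genes had a median of 0.55, above all 10000 random lists, with 11 of 22 members higher and 1 lower. The growth-factor-induced transcription factor genes Egr2, Egr1 and Fos were 5.33-fold, 3.46-fold and 2.88-fold higher, as was the ERK phosphatase gene Dusp6, at 3.83-fold. Interferon-stimulated genes had a smaller median, 0.30 (percentile 99.9, and 0.11 to 0.57 over the alternatives), with 10 of 31 members higher and 2 lower. Ifit1 was 2.49-fold higher, Gbp2 2.26-fold higher and Irf1 2.22-fold higher, whereas Ifi44 was 2.38-fold lower.

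Hypoxia and angiogenesis genes had a median of 1.26, above all 10000 random lists, with 14 of 21 measured members at least 1.5-fold higher and 4 lower. Car9, the carbonic anhydrase gene induced by hypoxia-inducible factors, was 12.4-fold higher, with a log2 difference of 3.64 ± 0.20. Egln3, which encodes a prolyl hydroxylase that acts on those factors, was 8.54-fold higher, Thbs1 7.63-fold and the vasodilator peptide gene Adm 6.45-fold. In the glycolysis list 10 of 21 members were higher and 0 lower by at least 1.5-fold, with a median of 0.56, again above all 10000 random lists. Pdk1, whose kinase restrains pyruvate entry into mitochondria, was 6.41-fold higher, the lactate exporter gene Slc16a3 5.55-fold, the phosphofructokinase gene Pfkl 3.37-fold and the glucose transporter gene Slc2a1 2.91-fold. The nuclear-encoded genes of oxidative phosphorylation had a median of -0.35, inside the central 95% of random lists (percentile 11.2), with 6 of 36 members lower and 0 higher.

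Of the 25 measured genes of cholesterol synthesis and uptake, which are targets of SREBP2, 20 were at least 1.5-fold higher on the choline-deficient array and 0 lower. Their median was 0.82, above all 10000 random lists. Nsdhl was 4.31-fold higher and Cyp51 3.85-fold, both genes of enzymes of the pathway's later steps. In the list of fatty acid synthesis and desaturation 8 of 18 members were higher and 0 lower, with a median of 0.13 at percentile 93.2, inside the central 95%. Its largest differences were in the acetyl-CoA synthetase gene Acss2, 3.51-fold higher, the desaturase genes Scd2 and Scd1, 3.09-fold and 2.74-fold higher, and the elongase gene Elovl6, 2.97-fold higher. Fatty acid oxidation and PPAR targets had a median of 0.32 (percentile 99.6, and 0.20 to 0.59 over the alternatives), with 7 of 22 members higher and 2 lower. Pdk4 was 2.88-fold higher and the medium-chain dehydrogenase gene Acadm 1.81-fold higher, and Hadhb was 1.69-fold lower. Lipid droplet genes had a median of 0.01 (percentile 74.4), with 1 of 17 higher, the monoacylglycerol lipase gene Mgll at 4.84-fold, and 5 lower. Their median was -0.27 after normexp (percentile 18.4), -0.14 with no filter (43.2), -0.11 with median scaling, -0.06 with the brighter probes and -0.03 after quantile normalization. Cholesterol efflux genes had a median of -0.23 (percentile 18.8), with Abca1 1.85-fold higher and the liver X receptor gene Nr1h3 2.42-fold lower.

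The genes of choline uptake and of the CDP-choline route to phosphatidylcholine went both ways. The plasma membrane choline transporter gene Slc44a1 (NM_133891, chromosome 4, 53573963 to 53574022) was 2.45-fold higher on the choline-deficient array, a log2 difference of 1.29 ± 0.21, with its 3 probes between 0.87 and 2.06. Pcyt1b (NM_211138, chromosome X, 90994629 to 90994688), encoding an isoform of the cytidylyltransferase that controls the rate of the route, was 4.97-fold higher (2.31 ± 0.21), while Pcyt1a, encoding the other isoform, differed by -0.002 ± 0.20. Chka, the choline kinase gene of the first step (NM_013490, chromosome 19, 3893508 to 3893567), was 3.13-fold lower, at -1.65 ± 0.20 with its 4 probes between -2.14 and -0.39. The choline transporter genes Flvcr1 and Flvcr2 were 2.49-fold and 1.75-fold lower. Smaller differences were -0.56 ± 0.20 for the second choline kinase gene Chkb, -0.59 ± 0.20 for Cept1, 0.18 ± 0.20 for Slc44a2 and 0.05 ± 0.21 for Chpt1, whose 2 probes had opposite signs. Over the 11 measured members, 2 were at least 1.5-fold higher, 4 lower, and the median of -0.002 was inside the central 95% (percentile 64.7). The median was -0.36 with the brightest probe of each gene (percentile 5.39) and with the brighter probes (8.28), -0.21 with no filter (53.9) and 0.27 with spike-in scaling, inside the central 95% each time. Slc44a3, Slc44a4, Slc44a5, Slc22a2 and Slc5a7, the high-affinity transporter gene of cholinergic neurons, were well above background on neither array. Of the CDP-ethanolamine and phosphatidylserine list, Pcyt2 was 1.86-fold higher and the median was 0.04 (percentile 68.2), but -0.10 after normexp (53.9) and -0.08 with median scaling. Phospholipid remodelling genes had a median of 0.24 (percentile 97.4), with the lysophosphatidylcholine acyltransferase gene Lpcat2 4.05-fold higher, Gdpd5, which encodes an enzyme that breaks down glycerophosphocholine, 3.16-fold higher and Gdpd1 2.15-fold lower. In the list of choline oxidation and the methionine cycle, 5 of 23 members were lower and 1 higher, with a median of -0.19 (percentile 29.4). The choline dehydrogenase gene Chdh, Dmgdh, Bhmt2 and Mat1a of this list were well above background on neither array, so the median does not cover them. The transsulfuration genes Cth and Cbs were 4.85-fold and 2.02-fold lower, Aldh1l2 2.04-fold lower and Ahcy, the gene of the hydrolase for S-adenosylhomocysteine, 1.65-fold lower.

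The integrated stress response list was lower on the choline-deficient array, with 12 of 29 members at least 1.5-fold lower, 2 higher and a median of -0.48 (percentile 0.13). The random lists had a median of -0.26, so the list's distance from it was -0.21. The medians of the list and of its random lists were -0.22 and -0.02 after cyclic loess, -0.27 and -0.06 after quantile normalization, and -0.20 and 0.01 with spike-in scaling. Ppp1r15a, whose product helps dephosphorylate the initiation factor eIF2, was 2.83-fold lower (-1.50 ± 0.20), the transcription factor gene Atf3 2.17-fold and Stc2 2.17-fold, while Ddit4, an inhibitor of mTORC1 signalling, was 2.06-fold higher. The autophagy list had 9 of 27 members lower, 3 higher and a median of -0.38 (percentile 0.74), where the random lists had -0.12, a distance of -0.26. These 2 medians were -0.32 and -0.01 after cyclic loess, -0.43 and -0.09 after quantile normalization, and -0.10 and 0.15 with spike-in scaling. Atg13, a gene of the initiating kinase complex, was 2.67-fold lower, Gabarapl2 2.43-fold lower and the cargo receptor gene Sqstm1 2.05-fold lower, while Rb1cc1, of the same kinase complex, was 2.07-fold higher. The lysosome list, with 9 of 26 members lower and 2 higher, had a median of -0.35 at percentile 4.19, inside the central 95%. Within it Gpnmb was 4.01-fold lower and the proton pump genes Atp6v1h and Atp6v0d1 were 2.58-fold and 2.19-fold lower. Endoplasmic reticulum chaperone genes had a median of -0.31 (percentile 8.95), with the chaperone gene Hyou1 2.56-fold lower.

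**Figure D2:**
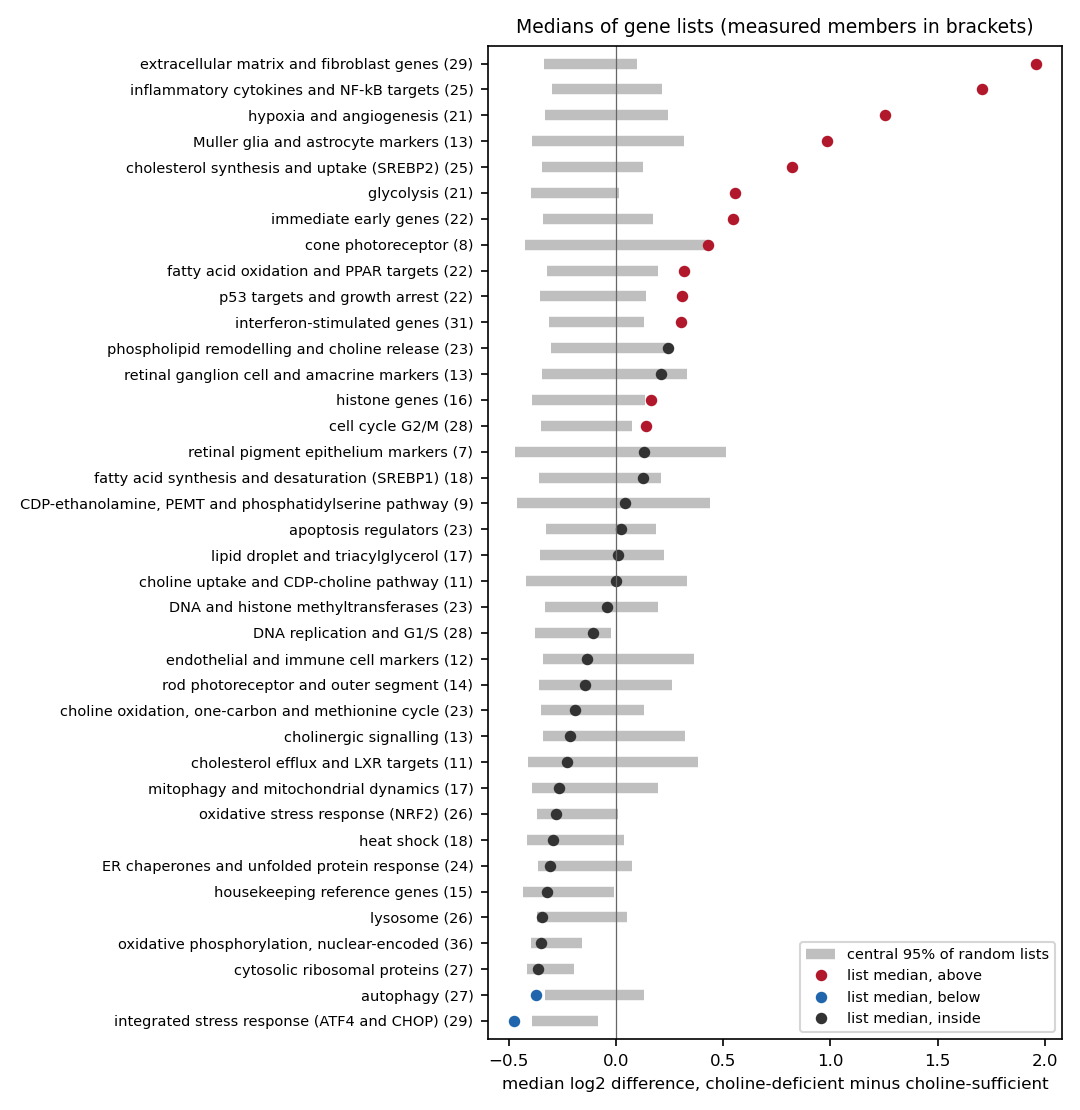
Median log2 difference of each of the 38 gene lists, choline-deficient minus choline-sufficient, with grey bars for the central 95% of 10000 random lists of the same size and matched expression. The medians of 13 lists lie above the bars, up to 1.96 for extracellular matrix genes, and those of integrated stress response and autophagy lie below at -0.48 and -0.38.

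The medians of 4 further lists were above the central 95% of random lists. The p53 and growth arrest list had a median of 0.31 (percentile 99.9, and 0.16 to 0.63 over the alternatives), with 10 of 22 members higher and 5 lower. The death receptor gene Fas was 6.94-fold higher, the cell cycle inhibitor gene Cdkn2b 2.84-fold, Gadd45g 2.13-fold and Sesn1 2.10-fold. The G2/M list had a median of 0.14 (percentile 99.3), which was 0.02 with median and 0.41 with spike-in scaling, with 5 of 28 members higher and 1 lower, among them the mitotic genes Cenpf and Ccnb2, 2.05-fold and 1.92-fold higher. Histone genes had a median of 0.17 (percentile 98.3), which was 0.05 and 0.44 with these scalings, with 5 of 16 members higher and 1 lower, of which H1f2 was 2.69-fold higher and H2aw 2.07-fold lower. The cone photoreceptor list had 8 measured members, 3 of them at least 1.5-fold higher, and a median of 0.43 at percentile 97.51, which moved inside the central 95% under 4 alternatives. The median was -0.16 after normexp background correction, so its direction turned there. Thrb, the thyroid hormone receptor gene that directs cone opsin choice, was 2.26-fold higher and the cone transducin subunit genes Gngt2 and Gnat2 were 1.65-fold and 1.47-fold higher. The log2 difference of the cone phosphodiesterase gene Pde6h, 0.87 ± 0.37, was -0.12 after normexp background correction. The cone list was written with 16 genes. Of these the cone opsin gene Opn1sw, Cngb3, Grk1 and Slc24a2 were well above background on neither array. Cnga3, Kcne2 and Guca1a were so only on the choline-deficient array, and Pde6c only on the choline-sufficient array. The rod list, of which 14 members were measured, had a median of -0.14 (percentile 34.6), and Crx and Nrl were well above background on neither array.

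The medians of the other lists were inside the central 95% of random lists. Negative medians smaller in size than 0.271 turn positive with spike-in scaling, which adds this constant to every gene. They were 0.21 for retinal ganglion and amacrine markers, 0.13 for retinal pigment epithelium markers and -0.14 for endothelial and immune markers. They were 0.02 for apoptosis regulators, -0.11 for DNA replication, -0.04 for DNA and histone methyltransferases, -0.22 for cholinergic signalling and -0.26 for mitophagy. Signs turned for ganglion and amacrine markers with no filter (-0.18) and after normexp (-0.09), and for apoptosis regulators with median scaling (-0.10). They also turned for DNA replication after cyclic loess (0.01) and for methyltransferases after cyclic loess (0.13) and quantile normalization (0.04). The medians were -0.28 for the NRF2 oxidative stress response and -0.29 for heat shock. They were -0.36 for cytosolic ribosomal proteins and -0.32 for housekeeping reference genes. The latter pair were negative under each scaling, but only -0.05 and -0.02 after cyclic loess. Within these lists, the apoptosis inhibitor gene Birc3 was 3.16-fold higher, the mitophagy receptor gene Bnip3 3.06-fold higher, and Dnmt3l and the nicotinamide methyltransferase gene Nnmt were 2.73-fold and 2.49-fold lower. Of 38 lists 13 were above and 2 below the central 95%, where unrelated lists of unrelated genes would give 1.9. Genes of a list can vary together, and some lists share genes, such as Apoe and Thbs1. The 1.9 is therefore no measure of chance differences between 2 cultures.

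A further 853 genes were well above background only on the choline-deficient array and 305 only on the choline-sufficient array. For these the fold was taken as a lower bound. It is the bright array's level over the higher of the dim probe's own level and the lowest level well above background on the other array. The bound, which uses scaled levels, was 2-fold or more for 158 and 128 of them. The background call itself is made before scaling, and the choline-deficient array was brighter, with a 75th percentile of 1609 against 1280. The counts of 853 and 305 therefore cannot be read as more genes being expressed without choline. On the choline-deficient array alone, the nucleotide-sugar receptor gene P2ry14 was at least 21.3-fold higher, Lrrc17 at least 13.1-fold, the Wnt ligand gene Wnt10a at least 10.8-fold and Cd83 at least 8.08-fold. The Wnt ligand gene Wnt6 was 9.86-fold higher there. On the choline-sufficient array alone, Ostn, which encodes the secreted peptide osteocrin, was 69.4-fold higher. The phosphatase gene Ppef1 was at least 53.4-fold higher there, Prr32 at least 47.9-fold, the pro-apoptotic gene Hrk at least 17.1-fold and Nyx, which encodes nyctalopin, at least 14.9-fold. For Ostn and Wnt6 the dim probe's own level was the higher. Their folds are therefore ratios to a signal not well above background, and not strict bounds.

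Before scaling, the difference between the arrays varied with brightness. The median over genes was 0.34 in the fourth of 10 equal groups by mean level, counted from the dimmest, and 0.03 in the brightest. The 8 spike-in probes well above background on both arrays, each with 32 spots, differed by -0.04 to 0.11.

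**Figure D3:**
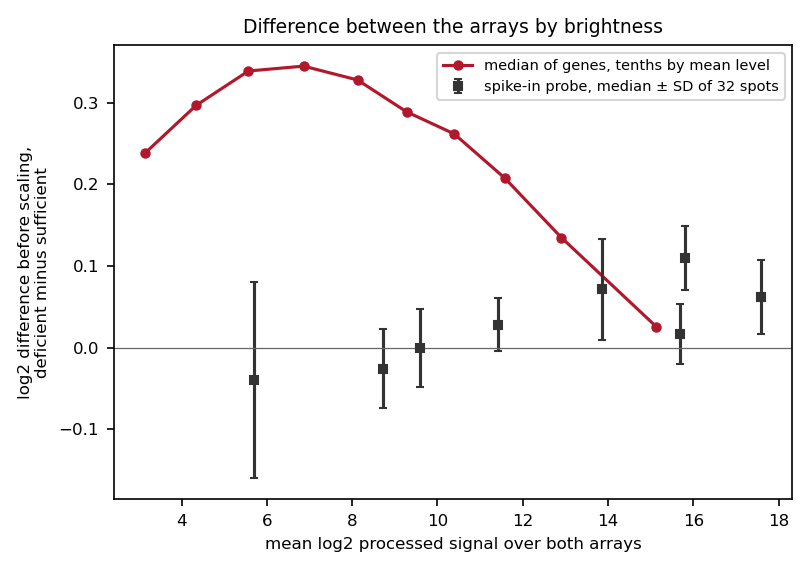
Log2 difference between the arrays before scaling (vertical axis) against mean log2 processed signal over both arrays (horizontal axis), as medians of 10 equal groups of genes by mean level and as spike-in probes with ± SD over 32 spots. The gene medians reach 0.34 among dim genes and 0.03 among the brightest, and the spike-in probes lie between -0.04 and 0.11.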

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

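The tests of the trend with brightness, on all spike-in probes and on gene lists, were chosen only after those results were seen. So was the bound that decides on the share held by the brightest probes, since the value met neither bound written beforehand. The tests of a defect in an area and of mixed-in fibroblasts were written beforehand.

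A spike-in probe that the comparison does not use, a104, was brighter on the choline-deficient array by 0.617 before scaling. It stood out because the 8 brighter spike-in probes differed by at most 0.11. It was near background, with 15 of its 32 spots well above background on the choline-deficient array and 5 on the choline-sufficient array. The other spike-in probe near background differed by 0.228 ± 0.154 (SE), with 1 and 0 spots well above background.

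Dimmer genes were brighter on the choline-deficient array relative to the brightest genes. A trend of hybridisation or scanning is argued against at the signals of the spike-in probes above background, because the 3 dimmest minus the 3 brightest of the spike-in probes above background gave -0.085 ± 0.009 (SE), where genes at the same signals gave 0.286. Below those signals it cannot be told apart from other causes, since the 2 spike-in probes near background minus the 3 brightest gave 0.36 ± 0.098 (SE) and genes gave 0.268, but few of these spots were well above background. Each SE here is over the 32 spots of a probe and leaves out the spread between probes. The 2 probes near background differed by 0.228 and 0.617, and the 3 brightest by 0.017 to 0.11. A larger share held by a few abundant genes on the choline-sufficient array is argued against as the whole cause, since the 100 brightest probes held 0.454 percentage points more of the signal there, which leaves all other probes a rise of only 0.007 log2. RNA quality, labelling and a difference in RNA make-up between the cultures stay open as untested.

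The matrix, hypoxia, glycolysis and cholesterol lists were higher on the choline-deficient array, and the integrated stress response and autophagy lists lower. For the first 4 lists the trend with brightness is argued against as the whole cause by the size of their medians. After cyclic loess these were 2.15, 1.34, 0.717 and 0.92, against 1.96, 1.26, 0.56 and 0.82 before. With the main scaling the medians of the 10 groups of genes by mean level ran only from -0.304 to 0.014. The upper ends of the central 95% of random lists were at most 0.31 after loess. Random lists were matched on mean level from the start, so lying above them after loess adds no support. For the stress response and autophagy lists the higher percentile after loess was 0.395. Their distances from the random lists' medians were -0.20 and -0.31, against -0.21 and -0.26 before. The matching on level means that these values could hardly move either. The lists' own medians were -0.22 and -0.32 after loess, against -0.48 and -0.38 before, so part of the stress response median went with the trend. A defect in an area of an array is argued against for the higher lists, since the fullest of 100 equal areas held 1.445% of the 3667 spots at least 2-fold apart, where the fullest area of all compared spots held 1.11%. Choline status, which the design names, stays open as untested, as do cell density, medium age and any other difference between the 2 cultures.

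Higher matrix genes may come from fibroblasts mixed into the choline-deficient cells, which were looked for with the abundant fibroblast transcripts Col3a1, Dcn and Lum. Col3a1 was 8.09-fold higher, Dcn, the lowest of those measured, differed by 0.581 ± 0.213, and Lum was well above background on neither array. The weak Dcn and the missing Lum go against fibroblasts rich in both, but Dcn was not at or below 0, and dim probes decide little. Fibroblasts poor in both transcripts and a different state of the 661W cells cannot be told apart here. Of the 30 genes written in the matrix list 29 were also above background in the choline-sufficient cells, and 1, Thbs1, is in another list.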

How the results depend on the processing

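Signal over background and the number of arrays set the limits: probes near background carry larger errors, and no setting replaces a replicate. No paired analysis was possible because each condition had 1 array and the labels give no shared replicate numbers. Of 2289 genes at least 2-fold apart (1520 higher, 769 lower on the choline-deficient array), the count was between 2243 and 2373 under median scaling, quantile normalization, cyclic loess, the value table, the brightest probe and the demand of over 2 errors, which removed no gene. The 95th percentile of the error was 0.316, so the demand of over 2 errors could hardly remove a gene already 2-fold apart and adds no support. The count was 1163 (742 higher, 421 lower) after normexp correction, whose offset draws dim values together. It was 4015 (1741 lower) with no filter, where 29607 genes were compared, and 1455 (976 and 479) among the 13617 genes of the brighter probes. It was 5733 (2932 and 2801) at 1.5-fold and 806 (607 and 199) at 3-fold, which follow from the sizes asked for. Spike-in scaling, added after the data were seen, gave 2292 higher and 385 lower, since it raises every difference by 0.271. Median and spike-in scaling move every gene by 1 constant and the value table moves none, so list percentiles cannot change there. The medians of the 15 lists outside the central 95% kept their sign under median, quantile, loess and spike-in scaling, though the cone median was -0.164 after normexp. The cone list, at percentile 97.51, went inside that range at 97.32 (quantile), 97.03 (loess), 80.04 (normexp) and 96.87 (brightest probe), and histone genes did so at 96.96 with the brighter probes. Phospholipid remodelling came to lie above at 97.66 (quantile) and 97.61 (no filter), apoptosis regulators above at 98.12 (quantile), and the lysosome list below at 1.51 (loess) and 0.88 (no filter). The cause was not tested. With the brighter probes 3 lists had under 5 members and no value. Of the named genes at least 1.5-fold apart 4 changed sign, each after normexp and each from a dim probe, with log2 values of -0.124 for Pde6h, -0.198 for Sag, -0.054 for Chrnb2 and -0.095 for Chat. Of those closer than 1.5-fold 1 changed sign with median scaling, 2 after quantile normalization, 1 after loess, 4 after normexp, 1 with the brightest probe and 2 with spike-in scaling, among them Pcyt1a at 0.269 there. Of 179 named genes a further 67 moved by more than their error after normexp, 20 after loess, 16 with the brightest probe, 14 after quantile normalization and 171 with spike-in scaling. Counting a gene as one-sided if any of its probes was bright gave 993 on the choline-deficient and 360 on the choline-sufficient array, against 853 and 305.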

Other observations

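Gene families, grouped by the letters of their symbols after the data were seen, overlap in part with the fixed lists, which hold 10 of 35 Col, 3 of 11 Ccl and 7 of 23 Cox genes. Of 175 families with at least 10 measured genes 17 lay above and 14 below the central 95% of random lists, where families of unrelated genes would give 8.75 in all. Members of a family can vary together, so the 8.75 is no measure of chance differences between 2 cultures. The matrix-related Col and Adamts families were higher on the choline-deficient array, with a median of 1.42 for 35 Col genes, of which 23 were at least 1.5-fold higher and 5 lower, and 0.64 for 12 Adamts protease genes, 6 of them higher and 0 lower. The matrix metalloproteinase genes (Mmp, 11 genes) lay inside the central 95%, with a median of 0.05 (percentile 69.5), 4 higher and 3 lower. The calcium- and membrane-binding annexins (Anxa, 11 genes) had a median of 0.59, the semaphorin guidance genes (Sema, 18 genes) 0.44, the Ccl chemokines (11 genes) 0.85, and the cilia-associated Cfap genes (23 genes) 0.30. Genes of the mitochondrial ribosome were lower, with medians of -0.41 for 49 Mrpl genes, 14 of them at least 1.5-fold lower and 1 higher, and -0.43 for 29 Mrps genes, 9 of them lower and 0 higher. The Cox genes had a median of -0.42, with 5 of 23 lower and 1 higher, and the Chmp genes of membrane scission -0.56, with 5 of 10 lower and 1 higher. The random lists' own medians were -0.21 for Mrpl, -0.19 for Mrps, -0.21 for Cox and -0.14 for Chmp, and between -0.16 and -0.04 for the higher families named above. All of these medians but that of Mmp kept their sign under the 4 other scalings, though those of Mrpl, Mrps and Cox were between -0.14 and -0.16 with spike-in scaling, which adds 0.271 to every gene. The lower families also held 13 Snhg genes (-0.56, percentile 0.27) and 204 olfactory receptor genes, Olfr (-0.165, percentile 0.33, but 0.107 with spike-in scaling). These lay further out than Mrps and Cox, at percentiles 0.51 and 0.605. Such a percentile alone therefore does not mark a biological theme.

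The highest family median was that of Klra, the Ly49 receptors known from natural killer cells. All 10 measured genes were higher, between 0.68 and 2.99, and their median was above all 10000 random lists. Of their 13 probes 8 share 15 or more consecutive bases with a probe of another Klra gene, so the number of Klra genes that differ is uncertain.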
